A study of Mus musculus with 23 samples.

How the data were processed

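Chromatin accessibility was measured by ATAC-seq in microglia sorted from the striatum of male mice aged 8 to 10 weeks. The series compares control offspring (CON) with offspring of dams exposed to maternal immune activation (MIA), each 18 hours after an intraperitoneal injection of saline (SAL) or of lipopolysaccharide (LPS) at 4500 endotoxin units per gram of body weight. The agent used for the maternal immune activation is not given in the sources used here. Cells were gated as live, CD11b+, CD45-low and P2RY12+ after removal of the meninges and digestion of the tissue with papain at 37 °C, per the labels' protocols. The series held 23 libraries, 5 CON_SAL, 7 CON_LPS, 6 MIA_SAL and 5 MIA_LPS, each with its own list of peaks.

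Per the submitters' processing notes, cutadapt, Bowtie2, Picard, SAMtools, MACS2 and DiffBind were used and the builds mm10 and GRCm38 were named; the versions and settings are not given in the sources used here. The deposited lists had no header. From their values, the authors' columns were read as the fold enrichment at the summit over the local background (a ratio), and the −log10 p and −log10 q of the peak. The others were an integer score that equals the whole part of 10 times the −log10 q, and the distance of the summit from the start of the peak. The deposited score was not used. Fold and −log10 p per peak are the authors' own values and served to rank peaks within a list and to describe libraries. The lowest deposited −log10 q was 1.301. No table of counts was used here, so the total number of reads per library is unknown. The background that the caller used, worked back from the fold and the −log10 p, came to between 1.94 and 2.99 fragment overlaps per base in the 23 libraries.

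The lists held between 33949 and 68312 peaks on chromosomes 1 to 19, X and Y. Since the number of peaks moves with depth and quality, every list was shortened to its best 33949 peaks by −log10 p. A window of 501 bp was centred on each summit, overlapping windows were removed with the best rank kept first, and windows with a peak in at least 3 of the 23 libraries were kept. This left 49123 of 74286 windows, called regions below; 16596 of them had a peak in all 23 libraries. A library had a peak in a region when a peak covered at least 50% of the region or had at least 50% of its own length inside it.

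Genes came from a table of mouse gene positions for GRCm38 with 21883 protein-coding genes and no strand, so the start of transcription could not be told from the end of the gene. In place of promoters, a region was placed at a gene end when it lay within 1 kb of either end of a protein-coding gene, otherwise in a gene body or between genes. A top region was named by the protein-coding gene with the nearest end within 100 kb. A region of a list was named by the list gene within 20 kb, even where another gene lay nearer. Neither name shows that the region controls the gene. Motif shares had been planned and were not run, since no genome sequence was used here.

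Before the data were examined, the tests, the 18 gene lists, the alternatives and the rule for naming genes were fixed. LPS was compared with saline in CON and in MIA offspring, and MIA with CON after saline and after LPS, by Fisher's exact test on the number of libraries with a peak. Both LPS contrasts together, and both MIA contrasts together, were tested with an exact conditional test of a common odds ratio, stratified by the other factor. All tests were two-sided. Regions entered a test when the number of libraries with a peak allowed a p of 0.01 or less. Their p-values were adjusted by Benjamini-Hochberg (BH), and an adjusted p under 0.05 was a call. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries.

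The size of the LPS response was compared between CON and MIA offspring in 2 ways. At matched numbers, regions with a peak in all of 5 LPS and none of 5 saline libraries, or the reverse, were counted over every such subset. For the LPS score, regions were chosen whose share of libraries with a peak differed by at least 0.75 between 4 LPS and 4 saline libraries of CON offspring, over all 175 subsets. The score of a library is the percentage of the LPS-higher regions with a peak minus that of the LPS-lower regions, and CON libraries were scored only with subsets that left them out. The null came from 100 assignments of the prenatal label within treatments, the real one included.

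The 18 gene lists held 374 entries for 363 genes, all matched by symbol: homeostatic microglia, NF-kB and acute inflammatory, interferon-stimulated, antigen presentation, disease-associated microglia, TLR4 signalling, immediate early and dissociation, myeloid transcription factors, complement and phagocytosis, glycolysis and hypoxia, border-associated macrophage, monocyte and neutrophil, neuron, astrocyte, oligodendrocyte lineage, endothelial, lymphocyte, and housekeeping. Another list also held 6 genes of the homeostatic list, 4 of the disease-associated list, 4 of the transcription factor list, 6 of the complement list, 1 of the glycolysis list and 1 of the housekeeping list. A locus was the gene with 20 kb on each side. Regions with a peak at the loci of a list were counted per library and compared with exact permutation tests, adjusted by BH over the 18 lists within a contrast. Differences of the response between CON and MIA used 100000 permutations of the prenatal label within treatments.

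Named genes are those of the 12 regions each way with the smallest p in each LPS contrast and the 5 each way in each MIA contrast, plus up to 4 genes per list with the smallest p in the LPS test over both offspring groups. Ties were broken by the larger difference, then by more libraries with a peak among all 23, then by position. This order prefers regions that were also open in the other prenatal group, so the values of named regions in that group are not representative of all called regions. Some regions that the rule picked are not reported here.

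The tests were checked on simulated data with the same 49123 regions and numbers of libraries. Libraries were drawn independently of each other there, and only regions open in a middle share of libraries were changed. With 200 changed regions, the contrasts of 2 groups recovered 0% of those differing by 96 points, and the stratified tests recovered 99.0% (LPS) and 100% (MIA). With 2000 changed regions, the contrasts of 2 groups recovered 77.6% to 80.3% of the differences of 96 points and 26.6% to 33.9% of those of 80 points. A contrast of 2 groups therefore finds few or no regions unless many change. When the response was removed in MIA offspring at 500 of 1000 simulated regions, the difference in the LPS score was 27.5 points (permutation p = 0.01).

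Alternatives were all deposited peaks, lists of 16974 peaks, ranking by fold, an overlap of 1 bp, and a summit inside the region. Further ones were a −log10 q of at least 5, no filter on the attainable p, regions in at least 1 library and strata of sorted cell number. The last were the replicate number as a block, 1 library per identity number, gene ends only, 100 kb around the gene, each library left out in turn, and limma on within-list ranks. In the limma fit each region's value was the rank of its peak in the list of 33949, and regions without a peak took the rank of the last peak. Leaving out the libraries of identity numbers 01 to 03 was added after the data were seen. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.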

Results

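ATAC-seq peaks were available for striatal microglia of 4 groups of adult male mice: control offspring after saline (CON_SAL, n = 5) or LPS (CON_LPS, n = 7), and offspring of immune-activated dams after saline (MIA_SAL, n = 6) or LPS (MIA_LPS, n = 5). LPS is a bacterial cell wall component that activates the receptor TLR4. The title of the series names a blunted reactivity of microglia after prenatal immune stress, which makes the size of the LPS response in MIA against CON offspring the central comparison. Values below are numbers of libraries with a peak in a region, on the mm10 genome, from lists of equal length.

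The deposited lists held 43902 ± 6896 peaks (SD, n = 5) in CON_SAL, 42459 ± 4524 (n = 7) in CON_LPS, 46784 ± 12459 (n = 6) in MIA_SAL and 51343 ± 11960 (n = 5) in MIA_LPS. None of the 4 contrasts of peak number passed an exact permutation test (LPS in CON p = 0.665, LPS in MIA p = 0.528, MIA after saline p = 0.684, MIA after LPS p = 0.104, BH-adjusted p = 0.414 or more). Without MIA_LPS replicate 3, the shortest list, the last had 13232 more peaks in MIA (exact permutation p = 0.00909, not adjusted). The median fold of the lists of equal length was 7.27 ± 1.76 in MIA_LPS and 5.87 ± 0.576 in CON_LPS (exact permutation p = 0.0455, BH-adjusted p = 0.182). Its other contrasts had an exact permutation p of 0.615 or more. Gene ends held 33.3% ± 2.68 of the peaks in CON_SAL, 33.4% ± 1.67 in CON_LPS, 34.0% ± 2.68 in MIA_SAL and 32.1% ± 1.96 in MIA_LPS. The 4 exact permutation tests of these shares gave p = 0.942, 0.216, 0.647 and 0.241 in the same order.

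Treatment separated the libraries. Regions shared by a pair of libraries came to 72.9% ± 4.04 of the regions open in either (SD, 56 pairs) within a group, 73.2% ± 4.07 (65 pairs) between MIA and CON libraries of the same treatment, and 66.5% ± 2.72 (132 pairs) between treatments. The first principal component, with 17.5% of the variance, had means of −32.9 ± 3.39 in CON_SAL and 28.1 ± 5.57 in CON_LPS (exact permutation p = 0.00126), and −31.8 ± 7.60 in MIA_SAL and 31.8 ± 6.01 in MIA_LPS (exact permutation p = 0.00216). MIA and CON libraries did not part on it (exact permutation p = 0.773 after saline and 0.293 after LPS).

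**Figure D1:**
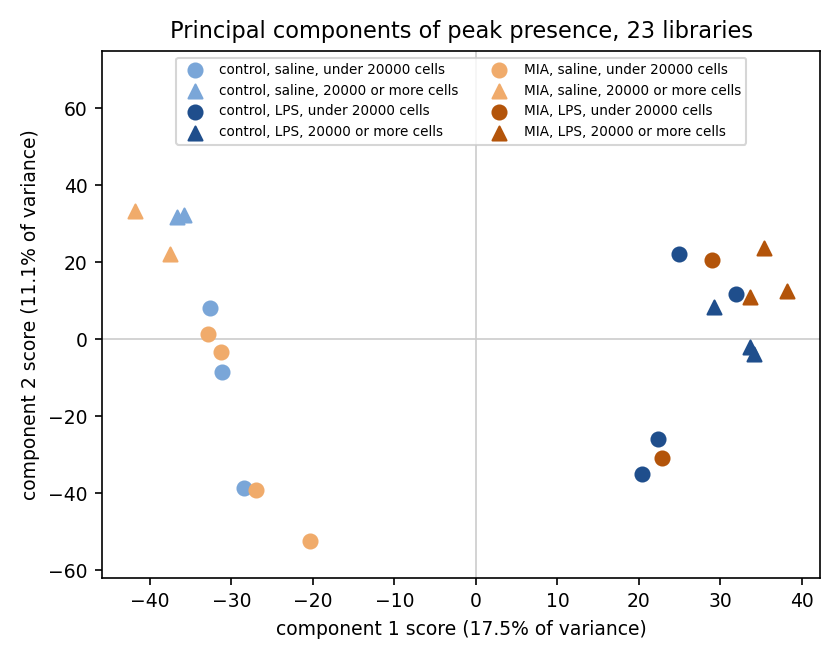
Scores of the 23 libraries on the first and second principal component of peak presence in the 49123 regions, in arbitrary units; each point is a library, colour gives the group and the symbol the number of sorted cells. Component 1 (17.5% of variance) parts LPS from saline libraries of both prenatal groups, and component 2 (11.1%) spreads libraries within each group.

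The second component, with 11.1% of the variance, followed the number of deposited peaks over the 23 libraries (r = 0.719, permutation p = 2.0e-04; rho = 0.836, permutation p = 1e-05, the smallest that the permutations can give). Without the 2 libraries farthest from the median number of peaks r was 0.713, and within libraries of fewer than 20000 sorted cells (n = 13) and of more (n = 10) it was 0.657 and 0.756. The number of sorted cells had r = 0.620 with the component (permutation p = 0.00214; rho = 0.642, permutation p = 0.00149), 0.591 without the 2 farthest, and 0.388 and 0.177 within the same classes of libraries. With 5 such relations tested, the BH-adjusted p of these r values were 0.0010 and 0.00535. The number of peaks had r = 0.502 with sorted cells (permutation p = 0.0130; rho = 0.414, permutation p = 0.0509), 0.464 without the 2 farthest, and −0.0970 and 0.0957 within the classes (BH-adjusted p of r 0.0163). It had r = 0.552 with the caller's background (permutation p = 0.00668; rho = 0.627, permutation p = 0.00186), 0.644 without the 2 farthest, and 0.47 and 0.651 within the classes (BH-adjusted p of r 0.0111). With the first component it had r = −0.0076 (permutation p = 0.974; rho = −0.0771, permutation p = 0.727), 0.0474 without the 2 farthest, and 0.436 and −0.418 within the classes. Since the treatments part on the first component, the pooled r hides a relation within saline libraries, where r was −0.848 (n = 11), against 0.336 within LPS libraries (n = 12). In the same order of treatments, sorted cells had r = 0.832 and 0.336 with the second component and 0.824 and 0.166 with the number of peaks. The number of peaks had 0.764 and 0.671 with the second component and 0.449 and 0.655 with the background. The 6 libraries lowest on the component, CON_SAL 3, CON_LPS 3 and 7, MIA_SAL 3 and 4 and MIA_LPS 3, carry the identity numbers 01 to 03 in the labels, whose meaning is not stated.

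In control offspring, LPS separated regions at Itgam, Sirpa and Slc7a11 completely from saline. Every CON_LPS library (7 of 7) and no CON_SAL library (0 of 5) had a peak 11734 bp from Itgam, the CD11b integrin by which the cells were sorted (chromosome 7, 128050656 to 128051156). The same 7 against 0 held within Sirpa, the receptor for the CD47 signal that restrains phagocytosis (chromosome 2, 129601024 to 129601524), and within Slc7a11, the cystine and glutamate exchanger (chromosome 3, 50402374 to 50402874). Pkm, the pyruvate kinase of glycolysis (chromosome 9, 59659638 to 59660138), followed, as did Bbc3, a mediator of apoptosis, and Klf9, a transcription factor induced by glucocorticoids. Further regions of this kind lay at Ehd1 and Trappc3 of vesicle traffic, at Wipf1 and Mtss1 of the actin skeleton, at the histone demethylase Kdm2a and at Mob3a. The reverse, a peak in 5 of 5 CON_SAL and 0 of 7 CON_LPS libraries, held within Apobec1, an RNA-editing deaminase (chromosome 6, 122595586 to 122596086), and within Cmklr1, the chemerin receptor (chromosome 5, 113619117 to 113619617). It also held within the transcription factor Mef2d (chromosome 3, 88156415 to 88156915), near Srm, the spermidine synthase, and at Nupl2, Otc, Rcsd1, Kcnk2, Fam171a1, Pip4k2a and Apbb1ip. Fisher's exact test called 656 of 5272 regions, 523 (79.7%) more in LPS and 133 more in saline, all at p = 0.00126 and adjusted p = 0.0101, the smallest that 7 against 5 libraries allow. Calls were therefore limited to complete separation. Without the filter on the attainable p none passed, because more regions were then tested. With lists of 16974 peaks 364 did (69.5% more in LPS), with a −log10 q of at least 5 402 (74.1%). Without identity numbers 01 to 03, an alternative chosen after the data were seen, 1289 passed (66.5%), and limma on ranks called 5073 (55.4%). Named calls ended at Cmklr1, Mef2d, Rcsd1 and Pip4k2a with all deposited peaks (−71.4 points, adjusted p = 0.172) and at Bbc3 and Sirpa with a −log10 q of at least 5 (65.7 points, adjusted p = 0.256). They also ended at Kdm2a with lists of 16974 peaks (adjusted p = 0.0828), at Trappc3 and Otc with ranking by fold (0.128), at Klf9 with the summit inside the region (0.112) and at Pkm with limma (0.0633). No gene list was enriched among the gained regions (smallest BH-adjusted p = 0.201, NF-kB list, Fisher's exact test).

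In MIA offspring, LPS separated regions at Tlr4, Ptprc and Mpeg1 completely from saline. All 5 MIA_LPS libraries and none of the 6 MIA_SAL libraries had a peak within Tlr4, the LPS receptor (chromosome 4, 66828613 to 66829113), and within Ptprc, the CD45 phosphatase (chromosome 1, 138158225 to 138158725). Likewise open were regions at the end of Mpeg1, a pore-forming protein of macrophages (chromosome 19, 12464162 to 12464662), and 1536 bp from Pecam1, an adhesion molecule of endothelium and leukocytes (chromosome 11, 106716567 to 106717067). The same 5 against 0 held at Hsf2, a heat shock transcription factor, at Id1, an inhibitor of transcription factors, at the galactosyltransferase B4galt1, at the actin regulator Abi1, and at Snx10, Grxcr1, Ankrd55 and E230025N22Rik. In the other direction, 6 of 6 MIA_SAL and 0 of 5 MIA_LPS libraries had a peak within Farp1 (chromosome 14, 121036013 to 121036513). The others lay within the integrin Itgae, within Tjp1 of tight junctions, within the deadenylase subunit Pan3, near the ephrin receptor Ephb3, and at Olfm5, Ctla4, Susd1, St3gal2 and Hs1bp3. Fisher's exact test called 895 of 5794 regions, 751 (83.9%) more in LPS and 144 more in saline, all at p = 0.00216 and adjusted p = 0.0140, again only complete separation. None passed without the filter on the attainable p, 533 with all deposited peaks (95.9% more in LPS), and 392 with a −log10 q of at least 5 (97.2%). Without MIA_LPS replicate 3 1369 passed. With lists of 16974 peaks, 806 passed (60.8%), and limma on ranks called 5078 (61.2%). With a −log10 q of at least 5 the calls ended at Ptprc, Abi1 and Grxcr1 (46.7 points, adjusted p = 0.563), Hsf2, Id1 and B4galt1 (83.3 points, 0.151), Ctla4 (−63.3 points, 0.346) and St3gal2 (−26.7 points, 0.803). With ranking by fold they ended at Ptprc, Abi1, Hsf2, Snx10 and Susd1 (adjusted p = 0.0708). No gene list was enriched among the gained regions (smallest BH-adjusted p = 0.110, Fisher's exact test).

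The responses of the offspring groups overlapped. Of the 12 regions gained in CON offspring named above, the one at Itgam had a peak in 4 of 6 MIA_SAL and 5 of 5 MIA_LPS libraries. The regions at Bbc3 and Klf9 had a peak in 5 of 6 and 5 of 5, and the one at Slc7a11 in 3 of 6 and 5 of 5. The one at Pkm ran the other way in MIA offspring, with 5 of 6 and 4 of 5. The Tlr4 region gained in MIA offspring had a peak in 2 of 5 CON_SAL and 7 of 7 CON_LPS libraries, and the Ptprc region likewise in 2 and 7. Those at Farp1 and Olfm5, lost in MIA offspring, ran the other way in CON offspring, with 4 of 5 CON_SAL and 7 of 7 CON_LPS libraries. The order of ties prefers regions open in the other prenatal group, so these examples do not represent all called regions. Among 2007 regions tested in both groups, 253 were called more in LPS in both, where 70.1 would be if the calls were independent (Fisher's exact p = 1.6e-130), and 21 more in saline in both, where 2.05 would be (Fisher's exact p = 1.5e-17). Regions near each other are not independent, so these p-values are too small. No region was called in opposite directions. In MIA offspring 522 of the 523 regions gained in CON offspring had a difference in the same direction, with a mean of 84.9 points, and in CON offspring 740 of the 751 gained in MIA did, with a mean of 75.9 points. Of the lost regions, 129 of 133 from CON had the same direction in MIA offspring (mean −63.4 points) and 140 of 144 from MIA in CON offspring (mean −61.1 points).

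Over both offspring groups, regions at Nos2, Tlr2, Trem2 and Cd80, named as members of gene lists, were gained with LPS. A peak was present in 12 of 12 LPS libraries (7 CON, 5 MIA) and 0 of 11 saline libraries (5 CON, 6 MIA) near Nos2, the inducible nitric oxide synthase (chromosome 11, 78916362 to 78916862), and near Tlr2, a receptor for bacterial lipoproteins (chromosome 3, 83844696 to 83845196). The same held near Trem2, a microglial lipid receptor (chromosome 17, 48355781 to 48356281). Cd80, a ligand for T cell costimulation, had such a region too (chromosome 16, 38458668 to 38459168). Others lay at Rxra, a nuclear receptor, Tnfsf18, a TNF family ligand, Srgap2, Tram2, Creg2, Fcrlb, Stum, Gm13547, Pip4k2a and Apbb1ip. The last 2 genes also had a region lost with LPS in CON offspring. Lost with LPS in both groups, with a peak in 11 of 11 saline and 0 of 12 LPS libraries, were regions within Tgfbr2, a receptor for TGF-beta (chromosome 9, 116122888 to 116123388), and within Golm1, a Golgi protein of the homeostatic list (chromosome 13, 59672109 to 59672609). Further lost regions lay within Scmh1, a Polycomb protein, besides Prim2, Dusp27, Vwa5b1, Lyar, Afp, Efcc1 and Cpped1. Each of these had an exact stratified p = 2.7e-06 and an adjusted p = 1.75e-04. The call at Cd80 ended with lists of 16974 peaks (39.2 points, adjusted p = 0.0984), and those at Scmh1 (−46.6 points, 0.0941) and Afp (−48.9 points, 0.101) with all deposited peaks.

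The exact stratified test called 4154 of 17546 regions, 2681 (64.5%) more in LPS and 1473 more in saline. It called 2719 with all deposited peaks (83.9% more in LPS), and 2532 with lists of 16974 peaks (57.7%). The counts were 2228 with a −log10 q of at least 5 (82.7%) and 2545 without the filter on the attainable p (72.1%). limma on ranks called 9818, of which 52.6% were higher in LPS.

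Inflammatory loci gained regions with LPS. At the loci of the NF-kB and acute inflammatory list, 30 of 94 tested regions were called more in LPS and 1 more in saline over both offspring groups, and 32 and 2 when adjusted over the list alone. That is 31.9% against 15.2% of the other tested regions (Fisher's exact p = 6.6e-05, BH-adjusted p = 0.00119 over the 18 lists), an enrichment test chosen after the calls were seen and the only 1 of the 18 to pass. Regions of 1 locus are not independent, and 5 of the gained ones lay at Socs3, so these p-values are too small. Of its 40 genes, 22 had a gained region, 1 (Nlrp3, an inflammasome sensor) a lost one and 17 neither. The cytokine gene Il1b had a region open in 6 of 7 CON_LPS, 5 of 5 MIA_LPS and no saline library, 16596 bp away (chromosome 2, 129387510 to 129388010, adjusted p = 5.4e-04 in the exact test). Socs3, a feedback inhibitor of cytokine signalling, had the same counts 3676 bp away (chromosome 11, 117962153 to 117962653). Of the 26 TLR4 signalling genes, 10 had a gained and 1 a lost region and 15 neither, with 12 and 1 of 49 regions called, also 12 and 1 when adjusted over the list alone. Tab1, an adaptor of the kinase TAK1, gained a region open in 12 of 12 LPS and 0 of 11 saline libraries that lies within its neighbour Syngr1. The loci of Map3k8 and Traf3, a kinase and an adaptor of the pathway, gained regions open in 12 of 12 and 1 of 11 (adjusted p = 5.6e-04), that of Map3k8 nearest to Mtpap (8312 bp). Ikbkg, the regulatory subunit of the IKK complex, gained 1 open in 12 of 12 and 2 of 11 (adjusted p = 0.00137), which also lay within G6pdx. The call at Map3k8 ended with all deposited peaks (55.2 points, adjusted p = 0.0510) and that at Ikbkg with a −log10 q of at least 5 (45.5 points, 0.180). The share of gained regions at the TLR4 list, 24.5%, did not pass against 15.3% elsewhere (BH-adjusted p = 0.387).

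**Figure D2:**
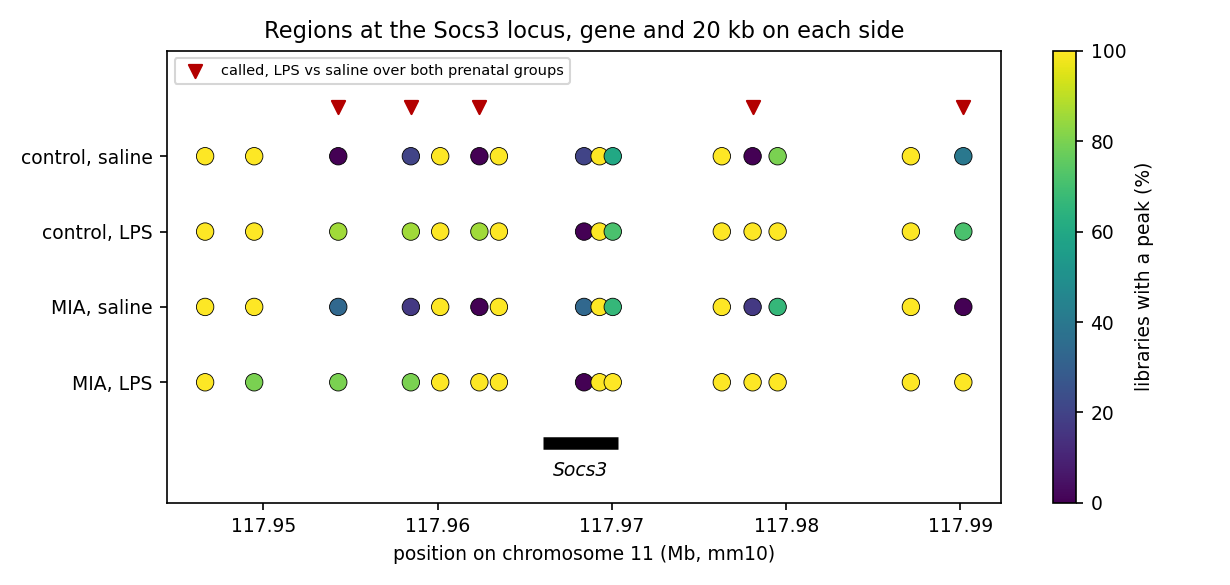
Regions at the Socs3 locus on chromosome 11 (position in Mb, mm10), the gene with 20 kb on each side; circle colour gives the percentage of libraries of each group with a peak and red triangles mark regions called between LPS and saline over both prenatal groups. Of 15 regions 6 were tested and 5 were called, all more in LPS.

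The single groups gave fewer calls at these loci. In CON offspring, 7 of 26 tested regions at the NF-kB list, 2 of 16 at the TLR4 list and 0 of 18 at the interferon-stimulated list were called, all more in LPS and the same when adjusted over the list alone. In MIA offspring 11 of 42 regions at the NF-kB list were called more in LPS (18, and 1 lost, adjusted over the list alone), 6 of 16 at the TLR4 list with 1 lost, and 4 of 23 at the interferon-stimulated list, the last 2 the same when adjusted over the list alone.

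Single regions at Ifi204, Csf1, Lpl and Cd36 were gained, while their lists did not pass the enrichment test. Gained were 28.8% of the tested regions of the interferon-stimulated list against 15.2% elsewhere (BH-adjusted p = 0.0575, Fisher's exact test), 18.9% for antigen presentation (0.666), 24.6% for disease-associated microglia (0.190) and 27.3% for complement (0.0566). In the interferon-stimulated list, 17 of 59 regions were gained and 2 lost (19 and 3 adjusted over the list alone), at 13 and 2 of 37 genes with 23 at neither. Ifi204, a DNA sensor, had a gained region open in 11 of 12 LPS and 0 of 11 saline libraries (adjusted p = 5.4e-04). The chemokine genes Cxcl9 and Cxcl10 share a region at the end of Art3, open in 5 of 7 CON_LPS, 4 of 5 MIA_LPS and no saline libraries (adjusted p = 0.00471). Its call ended with a −log10 q of at least 5 (43.1 points against 75.6, adjusted p = 0.312) and with limma (0.0667). The antigen presentation list had 7 of 37 gained and 2 lost (7 and 2 adjusted over the list alone), at 4 and 2 of 20 genes with 14 at neither. Cd86, a costimulatory ligand, and H2-T23 and Tapbp of the class I pathway were among the gained. The gene ends nearest to the regions at H2-T23 and Tapbp were those of H2-T24 (2977 bp) and Daxx (791 bp). Tapbp was not called with an overlap of 1 bp (37.4 points, adjusted p = 0.196). Of the disease-associated microglia list 17 of 69 regions were gained and 2 lost (23 and 2 adjusted over the list alone), at 14 and 2 of 24 genes with 10 at neither. Csf1, a growth factor of microglia, Lpl, the lipoprotein lipase, and Timp2, a protease inhibitor, each had 12 of 12 against 0 of 11. The complement and phagocytosis list had 21 of 77 gained and 3 lost (26 and 5 adjusted over the list alone), at 13 and 2 of 25 genes with 11 at neither. Cd36 and Msr1, scavenger receptors, and Itgb2, the partner of CD11b, were at 11 of 12 against 0 of 11. The call at Itgb2 ended with all deposited peaks (58.1 points, adjusted p = 0.0689).

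Regions of the homeostatic microglia list went both ways, 11 of 106 gained and 15 lost (16 and 18 adjusted over the list alone). That is 10.4% gained against 15.3% of the other tested regions, and 14.2% lost against 8.36%. Neither share passed Fisher's exact test (BH-adjusted p = 0.455 and 0.449). Of its 26 genes 9 had a gained region, 11 a lost one, 3 of these both, and 9 neither. Besides Tgfbr2 and Golm1, the loci of P2ry6, a nucleotide receptor of phagocytosis, and Bin1, a membrane-bending protein, had regions open in 12 of 12 LPS and 0 of 11 saline libraries. The region at P2ry6 had its nearest gene end at P2ry2, 4447 bp away. Gpr34, a lysophospholipid receptor, had 4 of 5 tested regions lost, and P2ry12, the sort marker, 1 of 9; both were picked out after their values were seen. Transcription factors of the myeloid list gained 18 of 94 regions and lost 4 (17 and 4 adjusted over the list alone), at 11 and 4 of 26 genes with 11 at neither. Ets2 was at 12 of 12 against 0 of 11, Irf8 and Smad3 at 12 of 12 against 1 of 11, and Runx1 at 11 of 12 against 0 of 11. Immediate early and dissociation genes had 9 of 45 gained and 5 lost (10 and 6 adjusted over the list alone), at 8 and 5 of 22 genes with 9 at neither. The phosphatase gene Dusp1 was at 12 of 12 against 0 of 11, Klf6 at 11 of 12 against 0 of 11, Klf2 at 11 of 12 against 1 of 11, and the chaperone gene Hspa1a (nearest end Hspa1b) at 9 of 12 against 0 of 11. The glycolysis and hypoxia list had 8 of 32 gained and 2 lost (9 and 3 adjusted over the list alone), at 5 and 1 of 20 genes with 15 at neither. The glucose transporter gene Slc2a1 was at 12 of 12 against 0 of 11, and Pfkfb3 and Hk2, glycolytic kinases, and Pgam1 (a region at a gene end of Exosc1) were among the gained. With a −log10 q of at least 5 the calls ended at Irf8 (54.2 points, adjusted p = 0.100), Hk2 (52.9, 0.0866) and Pgam1 (60.1, 0.0739). The call at Pgam1 also ended with ranking by fold, an overlap of 1 bp, limma and without identity numbers 01 to 03 (adjusted p = 0.114, 0.0951, 0.0734 and 0.0510). Klf2 ended with all deposited peaks (61.6, 0.0532) and Pfkfb3 with lists of 16974 peaks (39.2, 0.0984).

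Markers of other cells moved with LPS at single regions. Of the monocyte and neutrophil list 4 of 19 regions were gained and 2 lost (4 and 3 adjusted over the list alone), at 4 and 2 of 18 genes with 13 at neither. S100a8, a neutrophil alarmin, was open in 10 of 12 LPS and 0 of 11 saline libraries, and Mmp8, Cxcr2 and Elane, a collagenase, a chemokine receptor and an elastase of neutrophils, were among the gained, the region at Elane being nearest to an end of Prtn3 (1745 bp). Of the border-associated macrophage list 3 of 18 were gained and 0 lost, and 3 and 0 adjusted over the list alone, at 2 of 12 genes, F13a1 and Clec4n. In the same list Siglec1 (7 of 12 LPS and 1 of 11 saline libraries, adjusted p = 0.0967) and Folr2 (a gene end of Folr1, adjusted p = 0.273) did not pass. The neuron list had 2 of 26 gained and 3 lost (2 and 3 adjusted over the list alone), at 2 and 2 of 15 genes with 13 at neither, Foxp1 and Rbfox3 among the lost and Ppp1r1b (a region within Stard3) and Drd1 not called. The astrocyte list had 1 of 12 each way (1 and 1 adjusted over the list alone), Slc1a2 gained, Slc1a3 lost and Slc4a4 and Ntsr2 not called, with 10 of 12 genes at neither. The oligodendrocyte list had 1 of 16 each way (1 and 1 adjusted over the list alone), Mbp gained, Opalin (a region within Tll2) lost and Mog and Cnp (within Ttc25) not called, with 10 of 12 genes at neither. The endothelial list had 2 of 15 gained and 0 lost (2 and 0 adjusted over the list alone), both at Pecam1, with 11 of 12 genes at neither and with Flt1, Abcb1a (also a gene end of Rundc3b) and Kdr not called. The lymphocyte list had 2 of 14 gained and 1 lost (1 and 1 adjusted over the list alone), Trac (nearest end of a protein-coding gene Dad1) and Ms4a1 gained, Cd4 lost and Cd79a not called, with 9 of 12 genes at neither. The housekeeping list had 1 of 19 gained and 2 lost (0 and 1 adjusted over the list alone), Gapdh (a region within Iffo1) among the lost and Pgk1 (within Taf9b) and Tubb5 not called, with 13 of 15 genes at neither.

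Several of these calls ended under other settings. With all deposited peaks they ended at Rbfox3 (−47.5 points, adjusted p = 0.207), Slc1a3 (−55.8, 0.0861), Opalin (−37.9, 0.358), Cd4 (−12.8, 0.896) and Gapdh (−38.5, 0.313). With a −log10 q of at least 5 they ended at Cxcr2 (54.9, 0.100), Elane (46.2, 0.209), Pecam1 (52.9, 0.0866), Ms4a1 (37.4, 0.314), Slc1a3 (−55.2, 0.0504), Opalin (−23.9, 0.755), Cd4 (−37.2, 0.377) and Gapdh (−42.3, 0.271). Without the filter on the attainable p they ended at Slc1a2 (0.0505), Slc1a3 (0.0756), Mbp (0.0514), Ms4a1 (0.134) and Clec4n (0.0742). Clec4n also ended with 1 library per identity number (47.1, 0.106), Slc1a2 and Ms4a1 with the summit inside the region (0.0817 and 0.0502), Cd4 with ranking by fold (0.264) and Slc1a3 with limma (0.119). Leaving out 1 library ended the call at Ms4a1 for 18 of the 23 libraries (adjusted p = 0.0797 to 0.0984) and at Slc1a3 for each of the 5 MIA_LPS libraries (0.0503 to 0.0540). It ended the call at Clec4n without CON_SAL 1, 4 or 5 or MIA_SAL 2 (0.0503 to 0.0510). Other settings added calls among the regions not called. Siglec1 passed with the summit inside the region (56.2 points, adjusted p = 0.0283) and with a −log10 q of at least 5 (67.5, 0.0410), and Flt1 with an overlap of 1 bp (59.5, 0.0489). The region at Ppp1r1b passed with 1 library per identity number (68.8, 0.0395) and without numbers 01 to 03 (adjusted p = 0.0146). With limma the regions at Flt1 (0.00441) and Ppp1r1b (0.0454) were gained and those at Abcb1a (0.00733), Kdr (0.0243) and Pgk1 (1.8e-04) lost. Leaving out 1 library added a call at Flt1, Ppp1r1b, Tubb5, Pgk1 or Cd79a, depending on the library (adjusted p = 0.0182 to 0.0486).

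The number of open regions per library at the loci of a list rose with LPS in MIA offspring for 3 lists. The NF-kB list went from 143.7 ± 13.9 regions in MIA_SAL (SD, n = 6) to 180.4 ± 11.7 in MIA_LPS (n = 5; exact permutation p = 0.00216). The interferon-stimulated list went from 77.8 ± 9.85 to 97.0 ± 8.06 and the TLR4 list from 111.7 ± 6.71 to 125.8 ± 3.42 (exact permutation p = 0.00433 for both). Each of the 3 had a BH-adjusted p of 0.0260 over 18 lists. In CON offspring the same lists had 146.2 ± 13.4 regions in CON_SAL (n = 5) and 165.7 ± 8.32 in CON_LPS (n = 7; exact permutation p = 0.00758, adjusted p = 0.125) for NF-kB. They had 81.8 ± 9.55 and 93.1 ± 7.90 for interferon (exact permutation p = 0.0480, adjusted p = 0.201) and 111.8 ± 8.47 and 121.6 ± 3.95 for TLR4 (exact permutation p = 0.0139, adjusted p = 0.125). No list passed in CON offspring, where 4 had an unadjusted p under 0.05. Without CON_LPS replicate 3, 2 lists passed there (NF-kB 21.8 regions more and TLR4 11.0 more, both with adjusted p = 0.0390). In MIA offspring none of the 3 passed without MIA_LPS replicate 1, 3, 4 or 5, nor with gene ends only or with 100 kb around the genes. Fewer libraries raise the smallest possible p, but replicate 2 is not among these, and the cause was not tested. With all deposited peaks, as a percentage of open regions, 4 lists passed in CON offspring and the TLR4 list in MIA offspring did not pass (adjusted p = 0.582). With gene ends only, 2 lists passed in CON offspring.

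**Figure D3:**
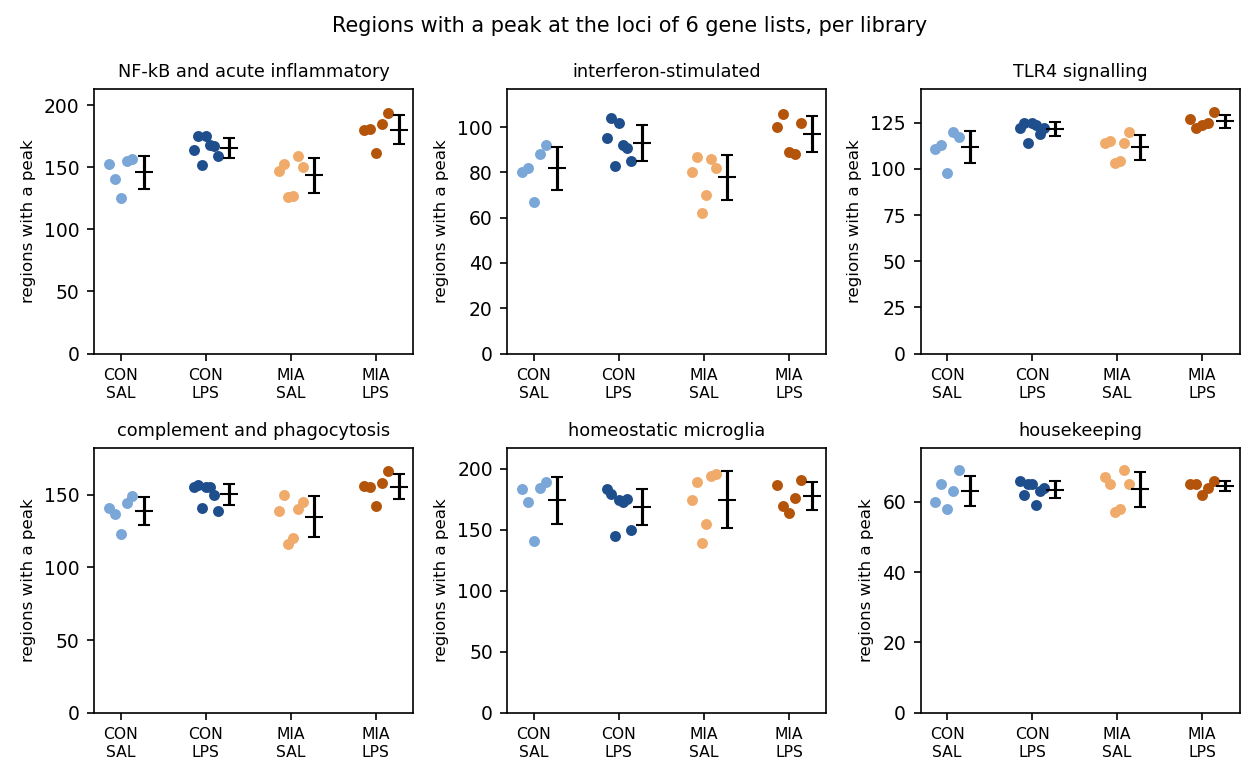
Number of regions with a peak per library at the loci of 6 gene lists (gene with 20 kb on each side) in the 4 groups; points are libraries, n = 5 to 7 per group, with mean and SD.

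With lists of equal length and 20 kb around the genes, no other list passed between LPS and saline after adjustment. The complement list had 138.8 ± 9.86, 150.3 ± 7.36, 135.0 ± 13.8 and 155.4 ± 8.65 regions in CON_SAL, CON_LPS, MIA_SAL and MIA_LPS (exact permutation p with LPS 0.0379 in CON and 0.0173 in MIA, adjusted p = 0.201 and 0.0779). The disease-associated list had 88.6 ± 10.6, 101.9 ± 11.0, 87.8 ± 9.79 and 100.8 ± 8.56 (exact permutation p = 0.0669 and 0.0390, adjusted p in MIA 0.117). With all deposited peaks, as a percentage of open regions, the complement list passed in CON (adjusted p = 0.0114) and the disease-associated list in MIA (adjusted p = 0.0130). The homeostatic list had 174.0 ± 19.3, 168.4 ± 14.8, 174.5 ± 23.2 and 177.4 ± 11.5 (exact permutation p = 0.590 and 0.820). The monocyte and neutrophil list had 30.6 ± 3.21, 31.6 ± 4.04, 29.3 ± 5.85 and 33.0 ± 3.54 (exact permutation p = 0.703 and 0.284), which leaves the gained neutrophil regions without a rise of the list as a whole.

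Regions that changed with LPS lay away from gene ends. Of the 2681 regions gained over both offspring groups 165 (6.15%) lay within 1 kb of a gene end, and of the 1473 lost ones 145 (9.84%), against 2527 (18.9%) of the 13392 tested regions that were not called (Fisher's exact p = 4.7e-70 and 8.7e-20). The regions at Mpeg1, S100a8, Msr1 and Ifi204 were among those at gene ends, while those at Nos2, Tlr2, Csf1 and Socs3 lay between genes. Gene bodies held 52.6%, 55.7% and 48.5% of the 3 classes and intergenic stretches 41.2%, 34.5% and 32.6%. Neighbouring regions are not independent, so the p-values are too small.

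No smaller LPS response of MIA than of CON offspring was found in either measure. Both measures count peak presence and not how strongly a region was open. At matched numbers of 5 LPS and 5 saline libraries, 859.5 regions separated completely in CON and 1016.5 in MIA offspring (659 and 816.5 of them more in LPS), a difference of −157 (permutation p = 0.490, two-sided, 95% of the permuted labels between −490 and 404). The LPS score, built from regions chosen in CON offspring, was −47.1 ± 12.5 in CON_SAL (SD, n = 5), 48.4 ± 6.87 in CON_LPS (n = 7), −47.5 ± 18.2 in MIA_SAL (n = 6) and 52.6 ± 5.02 in MIA_LPS (n = 5). The response was 100.1 points (SE 7.78, exact permutation p = 0.00216) in MIA offspring, which took no part in choosing the regions, and 95.5 points (SE 6.18) in held-out CON libraries. Their difference, CON minus MIA, was −4.63 points (SE 9.93, permutation p = 0.71, 95% of the permuted labels between −16.3 and 17.9). A score built in MIA offspring gave 94.7 points in CON offspring (SE 3.94, exact permutation p = 0.00126).

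The sign of the difference was not fixed. With all deposited peaks CON exceeded MIA offspring by 7.34 points (permutation p = 0.490) in the score and by 11.4 regions (permutation p = 0.99) at matched numbers, and without CON_SAL replicate 3 the score difference was 5.35 points. Region by region, an exact test of equal odds ratios, chosen after the results were seen, called 0 of 4973 regions (smallest adjusted p = 1, 33 with an unadjusted p under 0.05). A region open in every LPS library of both groups, such as those at Bbc3 and Klf9, could not enter this test, whatever its saline counts. The 0 calls therefore say nothing about such regions. With limma on ranks 1 region was called, in Lpcat2 near Capns2, where 51 of 100 assignments of the prenatal label gave at least 1 (highest other 28). Among the gene lists, the neuron list had the smallest p for a difference of response, 5.73 regions (permutation p = 0.00344, BH-adjusted p = 0.0619 over 18 lists), and the NF-kB list had −17.2 (permutation p = 0.106, adjusted p = 0.612). Neuron loci held 26.6 ± 1.52 regions in CON_SAL (n = 5), 28.4 ± 1.99 in CON_LPS (n = 7), 30.5 ± 2.17 in MIA_SAL (n = 6) and 26.6 ± 1.95 in MIA_LPS (n = 5). The neuron difference passed without CON_SAL 3, CON_LPS 5, CON_LPS 7 or MIA_LPS 4, and came to 1.71 regions with gene ends only.

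**Figure D4:**
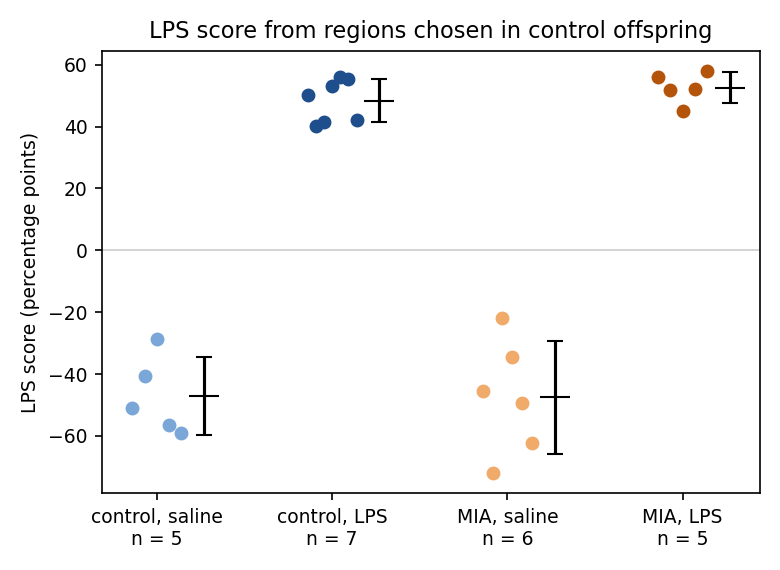
LPS score per library in percentage points, the share of LPS-higher regions with a peak minus that of LPS-lower regions, in the 4 groups; points are libraries, with mean and SD, and CON libraries are scored only with regions chosen without them.

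After saline, no region was called between MIA and CON offspring. The regions with the smallest p were near Itpkb, an inositol phosphate kinase, at the end of Zfp660, a zinc finger gene, and at Gm31513. Each had a peak in 6 of 6 MIA_SAL and 0 of 5 CON_SAL libraries. Regions near F2r, the thrombin receptor, and Azin1, the antizyme inhibitor, had 0 of 6 and 5 of 5 (exact p = 0.00216, adjusted p = 1). Bbc3 and Klf9 followed with 5 of 6 against 0 of 5, and Tfip11, Gosr2 and Xrcc4 with 1 of 6 against 5 of 5 (exact p = 0.0152, adjusted p = 1). Fisher's exact test called 0 of 4574 regions, 41 had an unadjusted p under 0.05, and limma on ranks called 0. The neuron list had more regions in MIA_SAL than in CON_SAL (30.5 against 26.6, exact permutation p = 0.0152, BH-adjusted p = 0.273). The endothelial list had fewer (15.2 ± 1.17 against 18.4 ± 2.61, exact permutation p = 0.0390, adjusted p = 0.351). Neither passed.

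After LPS, no region passed Fisher's exact test either. Ccl3, a chemokine gene of the inflammatory response, had a region 6535 bp away with a peak in 5 of 5 MIA_LPS and 0 of 7 CON_LPS libraries and in no saline library (chromosome 11, 83641058 to 83641558). The same held in Lpcat2, a gene of lipid mediators, near Capns2 (chromosome 8, 92881819 to 92882319). S100a6, a calcium-binding protein gene, Rrad, a small GTPase gene, and Cdhr3, a cadherin gene, had 5 of 5 against 0 of 7. Farp1 and Olfm5 had 0 of 5 against 7 of 7 (exact p = 0.00126, adjusted p = 0.593). Itgae and Pan3 followed with 0 of 5 against 5 of 7 (exact p = 0.0278, adjusted p = 0.903). The test called 0 of 4224 regions, and 130 had an unadjusted p under 0.05. limma on ranks called 22, all higher in MIA, among them the regions at Ccl3 (adjusted p = 0.0479) and Capns2 (adjusted p = 6.1e-05). Adjusted over the list alone, 1 of 24 regions at the NF-kB list was called and none at the other 17 lists. That list held 180.4 ± 11.7 regions in MIA_LPS and 165.7 ± 8.32 in CON_LPS (exact permutation p = 0.0328, BH-adjusted p = 0.591).

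Over both treatments, the regions at Capns2, at Ccl3 and within Zfp148, a zinc finger repressor, had a peak in 5 of 11 MIA libraries, all after LPS, and in 0 of 12 CON libraries (exact p = 0.00126, adjusted p = 1). Anapc13 and Epb41l2 were more often open in MIA, with 7 of 11 against 0 of 12 and 11 of 11 against 4 of 12. A region 35063 bp from Socs3 and a region within the transcription factor gene Tcf4 were open in 8 of 12 CON and 0 of 11 MIA libraries (exact p = 0.00153, adjusted p = 1). Mthfs and Lrrc8c were also more often open in CON. The exact stratified test called 0 of 15263 regions, 410 had an unadjusted p under 0.05, and limma on ranks called 1, the region near Capns2 (adjusted p = 0.0238). In simulated data this test recovered 100% of 100 changed regions with a difference of 96 points and 62.0% of 100 with 80 points. The tests after saline and after LPS recovered 0% of either when 200 regions changed, and 80.3% and 77.6% of the differences of 96 points when 2000 changed. The simulated libraries lacked any likeness by identity number, so recovery in the real libraries may be lower.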

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

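The left-out-library limits of the LPS score, the tests on the share of gained regions, the spread at a fixed number of sorted cells and the second-component gaps of the splits were chosen after the results were seen. Random splits of the libraries were used to ask whether chance can be excluded for each contrast of regions. For LPS against saline, only the real grouping of 100 reached its own number of calls (1 of 100 in each contrast): 656 in CON offspring with at most 0 in another split, 895 in MIA offspring with at most 0, and 4154 over both with at most 1. The splits compare total counts and not single calls, and they take no account of shared identity numbers. Within these limits, chance can be excluded for the number of LPS calls as a whole. For MIA against CON it cannot, since 67 of 100 splits had at least the 41 regions with an unadjusted p under 0.05 after saline (highest other 363, median 49), 28 had at least the 130 after LPS (highest other 235, median 113) and 39 at least the 410 over both treatments (highest other 1292, median 360). The 22 regions that limma called after LPS, Ccl3 and Capns2 among them, were matched or exceeded in 18 of 100 splits (highest other 187, median 4), so chance cannot be excluded for them.

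After saline and over both treatments the highest other splits had several times the real count, 363 against 41 and 1292 against 410, and point to a structure of the samples other than the prenatal group. They parted the libraries along the second principal component, by 44.8 after saline, the second largest gap of 99 other splits (median 11.4, real split 11.4), and by 30.5 over both treatments, the largest of 99 (median 11.4, real 11.1). The component came from the same peak presence as the counts, so these gaps describe the structure and are no separate support for it.

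Values that stood apart from their group were looked for in 104 groups of values, of which chance flags about 1 in 20, and 4 were found. MIA_LPS replicate 3 had −30.8 on the second component, with the next value at 10.9 and the highest at 23.8. CON_SAL replicate 3 had 127 regions at the myeloid transcription factor loci (next 159, highest 169), 14 at the endothelial loci (next 19, highest 21) and 23 at the lymphocyte loci (next 33, highest 34). A region in Lpcat2 near Capns2 had a response to LPS that differed between CON and MIA offspring in limma on ranks (adjusted p = 0.0238). At least 1 such call came in 51 of 100 assignments of the prenatal label (highest other 28), so chance cannot be excluded. The region was open in 5 of 5 MIA_LPS and in no other library, and groups without any peak have no spread in ranks.

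Read counts per region, RNA and cell function were not examined here, and peak presence does not grade how open a region is. In peak presence, the blunted reactivity named in the title of the series did not appear. A smaller response in MIA offspring cannot be excluded. The tests of this pattern were written before its values were seen, the limits without single libraries and with all peaks after. With the number of peaks as a covariate the LPS score differed by −0.852 points between CON and MIA offspring (SE 6.83). The upper limit, the difference plus 2 SE, was 12.8 points and lay below the 20 points set before. It was 8.30 without CON_SAL replicate 1, but 21.2 without CON_SAL replicate 3 and 21.7 with all deposited peaks, above the 20 points. The main setting thus argues against a difference in peak number that hides a smaller response. The settings above 20 points do not, so such a difference cannot be excluded. Without the covariate the upper limit was 15.9% of the control response, nearer than 1 SE to the 20% set before, so a smaller response missed for lack of libraries cannot be told apart from an equal response: the limit was 25.2% without CON_SAL 3, 22.8% without CON_SAL 2, 20.5% without MIA_SAL 6, 20.2% without MIA_SAL 2, 8.18%, 9.21% and 9.31% without CON_SAL 5, MIA_SAL 3 and CON_SAL 4, and 31.4% with all deposited peaks. Each SE here counts every library as independent, although libraries with the same identity number resembled each other on average, so these upper limits may be too low. The NF-kB list gave no smaller response in MIA offspring either (−17.2 regions, permutation p = 0.106).

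The excess of gained over lost regions with LPS was examined after it was seen, with both tests chosen then. Of the regions called by limma on within-list ranks, 52.6% were higher in LPS over both offspring groups (55.4% in CON, 61.2% in MIA), against 64.5% of the exact calls. Ranks in lists of the same length have a nearly fixed total, which pulls this share towards 50%, so an effect of the list length cannot be told apart from a true excess. LPS libraries had −1443 peaks against saline in CON offspring (exact permutation p = 0.665; 1061 without CON_SAL replicate 4) and 4558 more in MIA offspring (exact permutation p = 0.528). Both lie within their spread, so an effect of peak number cannot be told apart either.

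The spread along the second component was examined with 2 tests written before its values were seen and 1, on sorted cells, chosen after in place of correlations within cell-number classes (0.388 and 0.177), whose range of cells was narrow. Libraries labelled with 12500 sorted cells (n = 9) ranged from −39.1 to 20.7, with 93.6% of the SD of all libraries, which argues against the number of sorted cells as the only source, although within saline libraries it had r = 0.832 with the component (0.336 within LPS libraries). Loci of other cell types had r = −0.0852 with the component (permutation p = 0.699) and rho = −0.215 (permutation p = 0.321). Without the 2 farthest r was −0.164, and within the classes of fewer and more than 20000 cells it was 0.0360 and −0.534. All libraries had peaks at these loci, and no sample with a known share of other cells was available. The test therefore cannot decide whether other cells were in the sort. Of the variance within groups, 94.6% lay between identity numbers (median 52.8% when reassigned, permutation p = 3.0e-04), which is in line with a shared litter, day or other unit behind each number. What the numbers stand for is not stated, so the unit was not tested.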

How the results depend on the processing

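Adjusted over all regions tested, no region was called between MIA and CON offspring by the exact tests under any alternative run. LPS calls in CON offspring were 364 with lists of 16974 peaks, 402 with a −log10 q of at least 5, 0 without the filter on the attainable p, 1289 without identity numbers 01 to 03 (added later) and 5073 with limma. In MIA offspring they were 533 with all deposited peaks, 392 with a −log10 q of at least 5, 0 without the filter and 5078 with limma. Over both groups they were 2719, 2532, 2228 and 2545 with all peaks, 16974 peaks per list, the stricter q and no filter, and 9818 with limma. limma called 22 regions between MIA and CON after LPS and 1 over both treatments. Except for the filter, where more regions were tested, the cause was not tested.

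Replicate numbers as a block gave 1646 LPS calls over both groups and a gene-end share in CON of −0.207 points (exact permutation p = 0.813). Pairs of the same number correlated between −0.130 and 0.190. Their mean was above that of other pairs with LPS in CON (0.0227), with LPS in MIA (0.0323) and between MIA and CON after LPS (0.0395), and below it after saline (−0.0126). Whether the numbers pair libraries was not tested. Contrasts of 2 groups could not reach the attainable p of 0.01 in this block. With 4 against 4 libraries, neither could regions between MIA and CON after saline with 1 library per identity number or without numbers 01 to 03, nor with LPS in MIA without them.

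With all deposited peaks the difference CON minus MIA was 11.4 regions at matched numbers and 7.34 points in the score, and 4 lists passed in CON offspring as a percentage of open regions. With a −log10 q of at least 5, Itgae, Tcf4 and Drd1 turned to 2.86, 5.64 and −3.09 points (adjusted p = 1). Gene ends only gave 2 lists in CON and 0 in MIA offspring, −0.171 regions for the TLR4 list in CON and 0.0667 for the endothelial list between MIA and CON after saline. With 100 kb, 0 lists passed in MIA offspring and the neuron list there had 0.767. Without identity numbers 01 to 03, 0 lists passed in MIA offspring, where with 4 against 4 libraries a list alone could not reach an adjusted p under 0.05, so this count is no test of the lists. Motif shares were not run.

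With 1 library left out, calls ranged from 703 to 877 in CON, 947 to 1369 in MIA and 3468 to 4057 over both groups; the score difference from −9.79 to 5.35 points, above 0 without CON_SAL 3 or MIA_SAL 2 (0.257); matched numbers from −546 to −40.0; and the score in MIA from 95.3 to 112.3. Lists passing ranged from 0 to 2 in CON, 0 to 3 in MIA and 0 to 1 for the difference of responses. Peak-number differences ranged from −3033 to 1061 (LPS, CON; above 0 without CON_SAL 4), 984 to 8907 (LPS, MIA), −1423 to 5387 (MIA, saline; below 0 without MIA_SAL 2) and 5309 to 13232 (MIA, LPS). Gene-end shares ranged from −0.566 to 1.05 (LPS, CON), −2.78 to −1.22 (LPS, MIA), 0.0265 to 1.71 (MIA, saline) and −2.12 to −0.867 points (MIA, LPS; exact permutation p = 0.0455 without MIA_LPS 3).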

Other observations

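Some genes had several regions gained with LPS over both offspring groups, a ranking made after the results were seen. Socs3, the cytokine signalling inhibitor, had 5 of 6 tested regions called more in LPS, Cd86 had 4 of 6, the kinase gene Ikbke 4 of 6, and the neighbours Retn and Mcemp1, of resistin and a mast cell membrane protein, 5 of 6. Lpp, a focal adhesion gene, had the most, 7 of 13. Most lost regions were at Snd1, with 6 of 13 lost and 3 gained, and at Pard3b and Cask, each with 5 of 8 lost. The locus of Cask holds Gpr34 and its 4 of 5.

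Of the 22 regions that limma called higher in MIA than in CON offspring after LPS, a call that 18 of 100 splits matched or exceeded, 1 lay near Mertk, a phagocytic receptor kinase, with a peak in 1 of 7 CON_LPS and 5 of 5 MIA_LPS libraries (28.2 rank points, adjusted p = 0.0156). Others lay near Col4a1, a basement membrane collagen gene (34.2, adjusted p = 8.3e-04), F13a1 (42.8, adjusted p = 0.0240), Camk2a, a calcium-dependent kinase gene (46.7, adjusted p = 0.00968), and the chromatin gene Nsd1 (68.5, adjusted p = 0.00344).

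Libraries with the same identity number in the labels resembled each other beyond their group on average. The 10 such pairs had a mean residual correlation of 0.00802 against −0.0473 for other pairs (permutation p = 2.0e-04 within groups, and 0.0131 within groups and cell-number classes). Single pairs ranged from −0.146 to 0.123, and a pair of an MIA and a CON library after saline, which share no number, reached 0.190. The likeness by number was not separated from a likeness among all libraries of numbers 01 to 03. CON and MIA libraries never shared a number. Numbers 02, 03, 11, 14 and 15 were each carried by saline and by LPS libraries, so these numbers cannot stand for a single injected animal. The LPS contrasts did not pair libraries by number. If a number stands for a litter, p-values between CON and MIA libraries that count every library are too small.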
